A study of Mus musculus with 6 samples.

How the data were processed

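RNA was measured on 6 expression arrays, 1 array per sample, from mouse pancreas cells sorted by FACS for GFP. Per the labels, 3 samples came from KCiMist1G mice with wild-type p120 and 3 from KCiMist1G mice with the p120f/f genotype, each numbered as a biological replicate. Per the labels' protocols, mice aged 7 to 9 weeks received tamoxifen, which activates the Cre recombinase, and pancreases were digested and sorted 2 weeks later. RNA was isolated with a PicoPure kit and labelled with biotin, per the labels' protocols. The labels do not say whether a replicate was 1 animal or a pool, so p-values measure the spread between the samples as labelled.

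The authors deposited 1 table of log2 expression values with a row per probe group and a column per array. The submitters' processing notes name RMA and Partek, with no versions. RMA corrects background, normalizes between arrays and summarises probes to 1 log2 value, so small values are compressed and a fold change of a dim gene is understated. The genome build and the annotation behind the rows are not given in the sources used here. The deposited columns did not share 1 distribution: the array medians over all rows ran from 4.08 to 4.25. The table gives no detection calls and no slide or scan date, so signal over background and batches could not be tested, and precision is limited by the 3 arrays per group.

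The value table held 115830 rows. In the platform annotation, 25539 rows had 1 gene symbol, 2300 had several and 87991 were unnamed here. Of the single-symbol rows, 24941 matched a mouse reference gene table (assembly GRCm38.p6) by gene number, and 0 symbols needed an update. That table served only for names and for which genes neighbour each other, and no coordinates were taken from it. Each gene was represented by the row with the highest mean over the 6 arrays, which gave 20259 genes, 3109 of them with more than 1 row. Rows can also read pseudogenes or close paralogs, which these data cannot separate.

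The knockout minus wild-type difference was fitted for all genes with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no trend, not robust, no block, no filter on dim genes). P-values were adjusted with the Benjamini-Hochberg method over the 20259 genes, with a threshold of 0.05. Single values were also compared with an exact two-sided permutation test, which cannot give a p below 0.1 with 3 arrays against 3. Gene lists were compared with all other genes by limma's camera with a preset inter-gene correlation of 0.01, adjusted over the 35 lists, each with at least 4 measured members. Camera with the correlation estimated for each list, and fry, were run beside it. The 35 lists had 944 entries, of which 828 were measured. They covered junctions, pancreatic epithelial identity, other cell types that a sorted pancreas can hold, signalling, stress, metabolism and sex-linked genes. The result of 1 of the lists is not reported here by itself, although the counts of lists include it.

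The groups, tests, lists and the rule for named genes were fixed before the data were examined. Under that rule the text names Ctnnd1, then 12 genes per direction, then up to 4 members of each list described, those with the smallest p-values. The 12 were the largest changes past the threshold with all arrays of one group above all arrays of the other and a higher-group mean above the median gene. Places left open went to the smallest unadjusted p under the same other conditions, and none of the 24 genes named this way passed the threshold. Predicted genes (Gm numbers, Rik) and olfactory or vomeronasal receptors took no place.

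The fit was tested on simulated data with the spread of the real arrays, 20259 independent genes and 200 changed genes per size. It recovered 0% of changes of 0.5 log2 units, 51.5% of changes of 1 and 86.5% of changes of 2, with 0, 8 and 6 false calls. The alternatives were other normalizations, filters, row choices, variance models, array weights, thresholds and set tests, a replicate block, and each array left out in turn. Covariates for Xist and for leukocyte markers, and a set test without knockout array 1 with an estimated correlation, were added after seeing the data.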

Results

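Gene expression was compared between GFP-sorted pancreas cells of KCiMist1G mice, a mouse model of preinvasive pancreatic cancer, with wild-type p120 or with the p120f/f genotype that the labels call knockout. p120 catenin, encoded by Ctnnd1, binds the juxtamembrane part of classical cadherins and stabilises them at adherens junctions. The series asked how the transcriptome of the model differs with and without p120 catenin. Each group had 3 arrays, and the values were RMA log2 expression. Pearson's r between arrays, across 20259 genes that are not independent replicates, ran from 0.95 to 0.986. The first principal component held 51.7% of the variance and set knockout array 1 (-38.1) apart from knockout arrays 2 and 3 (28.4 and 37.1). The wild-type arrays lay between -14.9 and -4.16 on that component.

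Ctnnd1 itself was measured first, as a check of the labels. The arrays labelled knockout gave log2 values of 5.61, 6.61 and 6.38, and the wild-type arrays gave 5.87, 6.81 and 6.44. The means were 6.20 ± 0.52 (SD, n = 3) and 6.37 ± 0.47 (SD, n = 3). The difference of -0.17 (SE 0.32, 95% confidence interval -0.91 to 0.57) was smaller than the spread between arrays, with an exact permutation p of 0.6. In limma its adjusted p was 0.922. Without knockout array 1 the difference was 0.12, and without wild-type array 2 it was 0.045. Only 1 row named Ctnnd1, and a row that reads parts of the transcript outside the deletion checks nothing. These values did not show a loss of p120 on the arrays labelled knockout, so every direction given here is that of the labels. By Xist and Y-linked transcripts, given further on, the groups were also not balanced for sex.

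No single gene passed limma's adjusted threshold between the groups. The smallest adjusted p was 0.241. At an unadjusted p under 0.05 there were 708 genes, 467 higher and 241 lower on the arrays labelled knockout, against 1012.95 that 5% of the genes would give. A further quantile normalization gave 357 higher and 335 lower. All 3 knockout arrays lay above or below all 3 wild-type arrays for 1760 genes (8.69%), where chance gives 10%. The unadjusted count moved with single arrays: 5938 without knockout array 1, 448 without knockout array 2, 432 without knockout array 3 and 389 without wild-type array 3. With array weights, which put a weight of 8.57 on knockout array 2, 4797 genes passed. Without knockout array 1, Cd72 (-1.47, a B cell surface receptor) and Abhd18 (-1.91) were lower at an adjusted p of 0.0318. Abhd18 was picked out after its values were seen, and over all alternatives the smallest adjusted p of any gene ran from 0.00541 to 1.00. With all 6 arrays these differences were -0.83 for Cd72 and -1.31 for Abhd18, both at an adjusted p of 0.907.

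The 12 separated genes with the smallest p-values toward higher values on the knockout arrays were led by Cdk5rap1, Serpina6 and Slc15a2, with none past the threshold. Cdk5rap1, an enzyme that modifies mitochondrial transfer RNA, lay between 5.98 and 6.02 on the 3 knockout arrays and between 4.83 and 4.96 on the 3 wild-type arrays. Its difference was 1.11 (SE 0.11, adjusted p = 0.241). Serpina6, which encodes corticosteroid-binding globulin, differed by 1.39 (SE 0.17, adjusted p = 0.465). Slc15a2, a proton-coupled oligopeptide transporter, had the largest difference of this group at 2.05 (SE 0.34), with means of 8.26 ± 0.26 and 6.20 ± 0.71 (SD, n = 3). Reg3g, a secreted antimicrobial lectin, measured 10.15 ± 0.079 in knockout and 9.30 ± 0.40 in wild type (SD, n = 3). Cldn18, a claudin of gastric-type epithelium, measured 5.70 ± 0.20 and 5.07 ± 0.18 (SD, n = 3). Bloc1s6 differed by 0.74, Tmem181c-ps by 0.73, Abhd1 by 0.91, Zkscan8 by 1.01, Mrgprg by 0.51, Lrrc39 by 0.45 and Rps18 by 0.91. From Slc15a2 on, the adjusted p was 0.907. Other rows of Zkscan8 and Rps18 included differences of the opposite sign. The Rps18 row used averaged 5.46, near the median gene (5.43), against a wild-type mean of 9.50 for the ribosomal protein list. Its other rows differed by -0.18 to 0.16.

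Toward lower values on the knockout arrays, the 12 separated genes with the smallest p-values were led by Cd226, Itm2a and Rab6b, again with none past the threshold (adjusted p = 0.907 for all 12). Pira2, a paired immunoglobulin-like receptor with close paralogs that a row can share, differed by -2.76 (SE 0.62), from 6.73 ± 1.03 in wild type to 3.98 ± 1.00 in knockout (SD, n = 3). Cd226, an activating receptor of T and NK cells, differed by -0.89 (SE 0.14). Vps18, a subunit of the complexes that tether late endosomes, differed by -1.38 (SE 0.26). Ctsl, the lysosomal protease cathepsin L, measured 9.15 ± 0.26 in wild type and 8.21 ± 0.25 in knockout (SD, n = 3). Rab6b, a small GTPase of Golgi transport, differed by -1.09 (SE 0.20), and Itm2a by -0.96 (SE 0.16). Rps9 differed by -0.65, Zfp146 by -0.82, B3galt6 by -0.61, Igsf23 by -0.82, Pgm2l1 by -0.99 and Gemin7 by -0.63. Another row of B3galt6 differed in the opposite direction. Rps9 was the 1 list member that passed when adjusted over the list alone, in the ribosomal protein list.

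**Figure D1:**
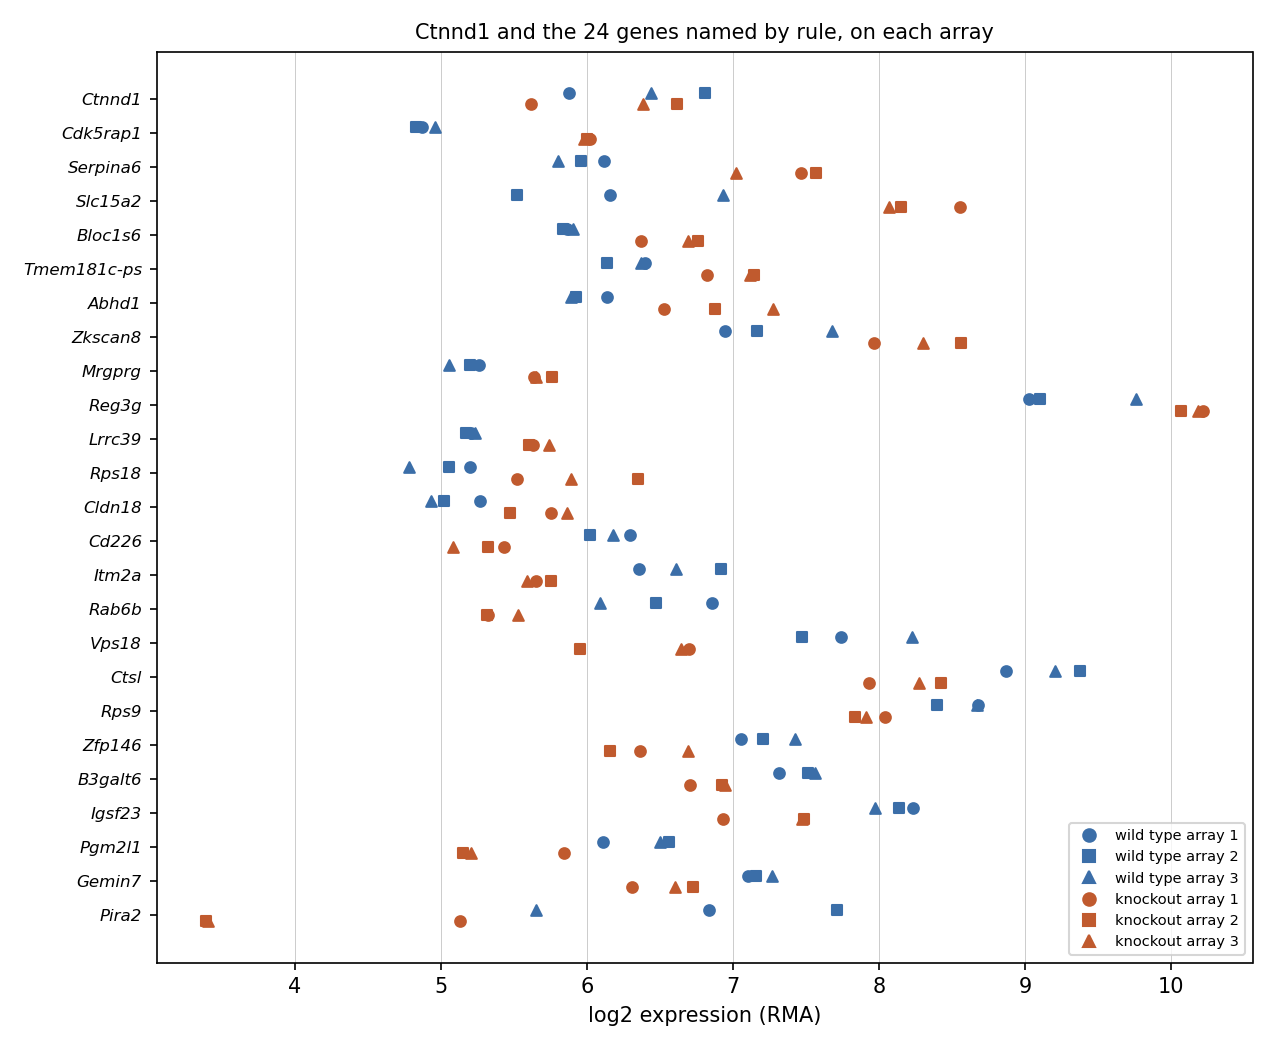
Log2 expression of Ctnnd1 and of the 24 genes named by rule, 1 point per array, with groups by colour and replicate numbers by marker. Ctnnd1 values of the groups overlap (5.61 to 6.61 and 5.87 to 6.81), while for each of the other genes all 3 arrays of one group lie above those of the other, with none past the adjusted threshold.

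Leukocyte, fibroblast and erythroid markers were lower as groups on the knockout arrays with camera's preset correlation, and none of these 6 lists was called with an estimated correlation (adjusted p = 0.731 for each). T and NK cell markers had a mean difference of -0.34 (17 of 19 members lower, camera adjusted p = 5.38e-09). Fibroblast and stellate cell markers had -0.35 (20 of 24 lower, adjusted p = 1.83e-07). Macrophage and monocyte markers had -0.27 (19 of 23, 0.00091), B and plasma cell markers -0.27 (15 of 16, 0.00104), neutrophil markers -0.22 (13 of 16, 0.0148) and erythroid markers -0.61 (8 of 8, 0.000992), the figures in brackets being members lower and camera's adjusted p. Endothelial markers (15 of 22 members higher, mean difference 0.08, adjusted p = 0.535) and islet markers (12 of 23 lower, -0.10, 0.0525) were not called in the fit as planned. Without wild-type array 2 endothelial markers were called higher (0.22, 0.0297). Islet markers were called lower without knockout array 2 (-0.18, 0.0015), knockout array 3 (-0.15, 0.0127) or wild-type array 1 (-0.16, 0.00579), and with a replicate block (0.0364), and their mean was 0.032 without knockout array 1. With an estimated correlation neither list was called with all 6 arrays. No member of any list passed over all genes. At an unadjusted p under 0.05 there were 3 T and NK members, 4 fibroblast members and 3 islet members, all lower. Cd3g, a T cell receptor subunit, differed by -0.72 (SE 0.24) and Cd3d by -0.37 (SE 0.14). Thy1 differed by -0.44 (SE 0.12) and the matrix protein gene Postn by -0.98 (SE 0.39), both in the fibroblast list. The smallest p-values elsewhere belonged to Tyrobp (-0.59) and Cd163 (-0.40) among macrophage markers, Ngp (-0.82) and Ltf (-0.51) among neutrophil markers, Cd72 (-0.83) and Cd79b (-0.45) among B cell markers, and Car1 (-1.46) and Tfrc (-0.35) among erythroid markers. Some of these rested on 1 array: Cd163 was -0.044 without wild-type array 2, and without wild-type array 3 Car1 was -0.34 and Tfrc -0.13.

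These markers did not separate the groups array by array. The mean over 74 leukocyte genes was 7.61 on knockout array 1, 6.43 and 6.45 on knockout arrays 2 and 3, and 7.08, 7.22 and 7.04 on the wild-type arrays. The exact permutation p of the list means was 0.2 for T and NK cells, 0.4 for fibroblasts and 0.5 for macrophages, with 3 arrays per group. Erythroid markers rested on wild-type array 3, whose list mean was 6.81 against 5.08 and 5.21 on the other wild-type arrays.

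**Figure D2:**
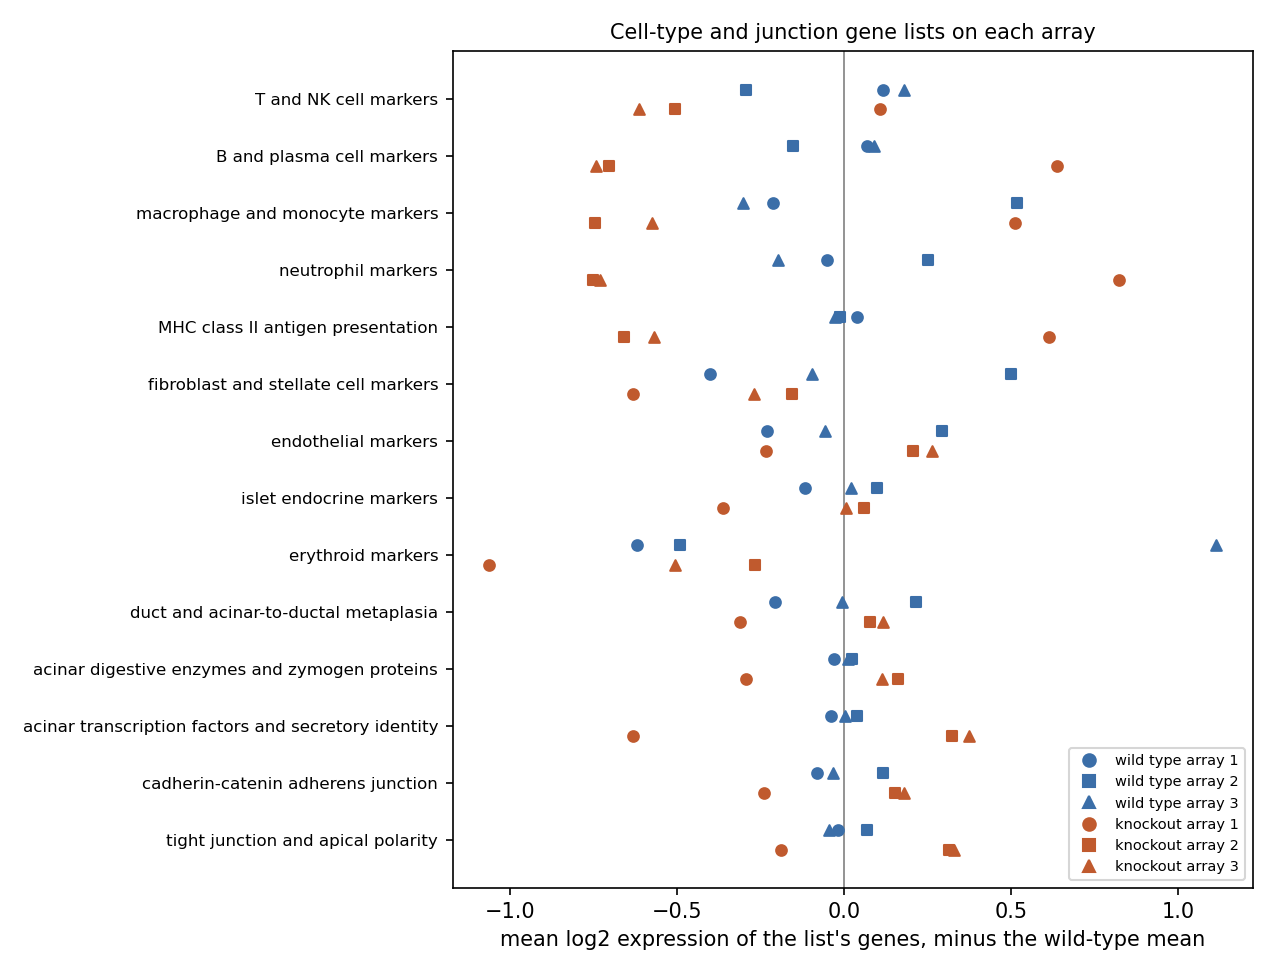
Mean log2 expression of 14 gene lists on each array, minus the wild-type mean of the list, with groups by colour and replicate numbers by marker. Knockout array 1 lies above knockout arrays 2 and 3 for the leukocyte and MHC class II lists. It lies below them for the epithelial lists and also for the fibroblast, endothelial, islet and erythroid lists.

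Cell cycle, inflammatory, mesenchymal and stress response lists were also lower on the knockout arrays by the preset-correlation test, and none of these 6 lists was called with an estimated correlation (adjusted p = 0.731 for each). Cell cycle genes had a mean difference of -0.13 with 34 of 44 members lower (adjusted p = 7.77e-05), where Pcna, the replication clamp, differed by -0.53 (SE 0.21) and Ccne2 by -0.24 (SE 0.12). NF-kB targets had -0.17 with 23 of 29 lower (0.000942), with the cytokine gene Tnf at -0.67 (SE 0.21) and Relb in the opposite direction at 0.37 (SE 0.18), although other rows of Relb were below 0. Interferon response genes had -0.14 with 18 of 26 lower (0.00209), including Irf1 at -0.44 (SE 0.16) and Gbp2 at -0.54 (SE 0.30). Immediate early genes, which also respond to tissue dissociation, had -0.13 with 19 of 27 lower (0.00209), with Klf4 at -0.81 (SE 0.26) and Junb at -0.29 (SE 0.12). Epithelial-mesenchymal transition genes had -0.13 with 18 of 24 lower (0.0154), with the matrix protease Mmp2 at -0.80 (-0.43 without wild-type array 2) and the matrix protein Tnc in the opposite direction at 0.43. This list moved with the fibroblast markers on wild-type array 2: its mean was 6.27 there against 5.90 and 5.90 on wild-type arrays 1 and 3, and the fibroblast mean was 6.60 against 5.70 and 6.01. Unfolded protein response genes had -0.05 with 17 of 27 lower (0.0154), with Syvn1 at -0.24 and Dnajb9 at -0.23. The median difference over all genes was 0.055, and camera compares a list with all other genes, so small list means should be read against that shift. Median members of the NF-kB (0.70), cell cycle (0.42) and interferon (0.41) lists were higher on knockout array 1 than on the mean of knockout arrays 2 and 3.

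Of the 13 lists called, all lower, 0 were called with an estimated correlation or by fry, whose smallest adjusted p was 0.935 for one direction and 0.846 for either. Only the T and NK list and the fibroblast list were called in every fit that left out 1 array, with largest adjusted p of 0.000443 and 0.0297. Their sizes moved with single arrays: the fibroblast mean was -0.10 without wild-type array 2 and -0.56 without wild-type array 1, and the T and NK mean was -0.20 without knockout array 3 and -0.56 without knockout array 1. The other 11 lists each lost the call in at least 1 such fit. Without knockout array 1, these were the erythroid (0.12) and unfolded protein response (0.5) lists. Without knockout array 2, they were the B and plasma cell (0.323), cell cycle (0.0599), epithelial-mesenchymal transition (0.09), immediate early (0.0574), interferon (0.127), macrophage (0.512), neutrophil (0.749) and NF-kB (0.136) lists. Without knockout array 3, they included the B and plasma cell (0.484), cell cycle (0.111), epithelial-mesenchymal transition (0.0919), immediate early (0.146), interferon (0.161), macrophage (0.107), neutrophil (0.833), NF-kB (0.113) and unfolded protein response (0.0919) lists. Without wild-type array 2, they included the epithelial-mesenchymal transition (0.643), immediate early (0.151), macrophage (0.643) and neutrophil (0.194) lists. Without wild-type array 3, they were the cell cycle (0.11), erythroid (0.63), interferon (0.806) and unfolded protein response (0.199) lists. In some of these fits the difference itself was close to 0 or above it. The neutrophil mean was 0.045 without knockout array 2 and 0.035 without knockout array 3, the macrophage mean -0.012 without wild-type array 2, the interferon mean 0.0090 without wild-type array 3, the unfolded protein response mean 0.032 without knockout array 1 and the epithelial-mesenchymal transition mean -0.0058 without wild-type array 2. The macrophage mean was -0.033 and the NF-kB mean -0.027 without knockout array 2, the B and plasma cell mean -0.033 without knockout array 3, and without wild-type array 3 the cell cycle mean was -0.042 and the erythroid mean -0.056. With all 6 arrays, a further quantile normalization ended the calls of the neutrophil (0.0605), immediate early (0.0605), epithelial-mesenchymal transition (0.0551) and unfolded protein response (0.115) lists. Among genes above the median level the neutrophil (0.149), immediate early (0.0809) and unfolded protein response (0.223) lists were not called, and over all rows the neutrophil (0.0533), epithelial-mesenchymal transition (0.0574) and unfolded protein response (0.125) lists were not. The unfolded protein response list was also not called above the 25th percentile of level (0.0637) or with array weights, where its mean was 0.075 (0.95), nor were erythroid markers with array weights (0.116). Over all alternatives the adjusted p of the called lists ran from 1.04e-16 to 0.95. The count was 8 without knockout array 2 and 5 without knockout array 3. Without knockout array 1 it was 16, of which 11 were among the 13, with 13 lower and 3 higher (desmosome, tight junction and acinar transcription factors). The 2 lower lists that were new there were MHC class II (-0.62, adjusted p = 2.75e-08) and chemokines (-0.27, 0.00149). That fit gave 0 with an estimated correlation (smallest adjusted p = 0.253).

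Epithelial junction and identity lists were not called in the fit as planned, with all 6 arrays and the preset correlation. Tight junction and apical polarity genes had a mean difference of 0.15 with 25 of 30 members higher (camera adjusted p = 0.0869), including Cldn18 and Cldn4, the latter at 0.64 (SE 0.20). That list was called higher with all 6 arrays after a further quantile normalization (0.0115), among genes above the median level (0.0239) or the 25th percentile (0.0474), with the mean of rows (0.0267), the row of largest interquartile range (0.0468), a replicate block (0.0465) or array weights (0.000357). It was not called with arrays shifted to 1 median (0.0717), over all rows (0.164), on ranks (0.143), with an estimated correlation (0.787) or by fry (0.935). Its mean moved with single knockout arrays: 0.32 without array 1 (0.000112), 0.068 without array 2 (0.689) and 0.061 without array 3 (0.484). Adherens junction genes had 0.03 with 17 of 23 higher (0.944), with Nectin4 at 0.19 (SE 0.16) and Lima1, which links junctions to actin, at -0.33 (SE 0.24). Desmosome genes had 0.12 with 13 of 14 higher (0.302), and 0.27 with array weights (0.0176). With an estimated correlation and equal weights the desmosome adjusted p was 0.856. Acinar digestive enzymes had -0.0067 (0.342), with Pla2g1b, the secreted pancreatic phospholipase, at 11.87 ± 0.38 in knockout and 11.71 ± 0.087 in wild type (SD, n = 3), and Dnase1 at a difference of 0.11. Acinar transcription factors and secretory genes had 0.02 (0.522), with Xbp1 at 0.18 (SE 0.13) and Pdia2 at -0.33 (SE 0.27). This list was called higher with array weights (0.31, adjusted p = 0.00181) and without knockout array 1 (0.35, 1.53e-05), and lower without knockout array 2 (-0.13, 0.016) and without knockout array 3 (-0.16, 0.00669), so its direction depended on single knockout arrays. With an estimated correlation it was called neither with all 6 arrays (0.95) nor without knockout array 1 (0.259). Without knockout array 2 the enzyme list was lower (-0.09, 0.0261). Duct and metaplasia genes had a mean of -0.04 and a median of 0.04 (0.318), with Wfdc2 at 0.41 (SE 0.16) and Car2 at -0.84 (SE 0.41, and -0.32 without wild-type array 3), and the list was lower without wild-type array 1 (-0.14, adjusted p = 0.0187). For the adherens junction, acinar transcription factor and sphingosine-1-phosphate lists the mean was above 0 while camera, which compares a list with all other genes, put it lower. Pdia2 was -0.023 without knockout array 1, Pla2g1b differed by 0.0047 without knockout array 3, and Lima1 by -0.11 without wild-type array 2. Of 37 list members named by rule, 27 moved by a factor above 1.5 in at least 1 fit that left out an array. Of the 24 separated genes 0 did, which their selection for complete separation and small p-values largely fixed in advance. These counts therefore do not compare stability. The members of the acinar transcription factor list were lower by a median of 1.02 on knockout array 1 than on the mean of knockout arrays 2 and 3.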

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

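The Xist and leukocyte covariates and the set test without knockout array 1 with an estimated correlation were chosen after seeing the data. Of the comparisons of Ctnnd1, 63 other named genes and 21 described lists with their alternatives, 1461 kept direction and side of the threshold, 68 gained a call, 81 lost one and 31 reversed, 3 of them for Ctnnd1. The trend and robust settings did not enter the list test, so for the 21 lists that alternative repeats the planned fit and is counted as kept. The 24 separated genes kept their sign in 451 of 452 refits, which their selection for complete separation largely fixed in advance. They passed the threshold only with array weights, where all 24 did, and otherwise their smallest adjusted p was 0.0509.

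In limma 0 genes passed with all 6 arrays (708 at an unadjusted p under 0.05). Array weights gave 4797 genes (8729 unadjusted). The weight estimation stopped before its tolerance was reached, and the weights were 0.142, 8.57 and 0.677 for the knockout arrays and 1.03 to 1.1 for the wild-type arrays, so that fit rests mostly on 1 knockout array. An unadjusted p with at least a 2-fold difference gave 34. The unadjusted count was 242 for genes above the median level and 449 above the 25th percentile, where fewer genes were tested, 5742 over all rows, where more were, and 1186 with Xist as a covariate, whose cause was not tested. With the leukocyte marker level as a covariate it was 1050 (605 higher, 445 lower) with 0 genes adjusted and a smallest adjusted p of 0.111. Leaving out 1 array gave 0 to 2 genes adjusted, 389 to 5938 unadjusted and 5 to 17 lists. The highest gene counts came without knockout array 1. Against 13 lists with the preset correlation, an estimated correlation gave 0, fry 0, and the fit without knockout array 1 with an estimated correlation 0.

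Ctnnd1 was 0.20 with array weights and ran from -0.42 to 0.12 when 1 array was left out. Dnase1 was -0.0011 after a further quantile normalization, and Pdia2 0.0047 with array weights. With the row of largest interquartile range, B3galt6 was 0.34 and Relb -0.13. For lists, camera's direction against all other genes turned at these mean differences. Adherens junction: 0.027 above the 25th percentile, 0.041 with the mean of rows, 0.055 with the row of largest interquartile range, 0.15 with array weights, 0.087 without wild-type array 2, and 0.17 without knockout array 1 with either correlation. Acinar enzymes: 0.15 with array weights and 0.14 without knockout array 1 with either correlation. Acinar transcription factors: 0.024 after quantile normalization, 0.015 above the median level, 0.31 with array weights and 0.35 without knockout array 1 with either correlation. Duct and metaplasia: -0.044 above the median level, 0.072 with array weights, 0.067 without wild-type array 2 and 0.10 without knockout array 1 with either correlation. Of the 6 fits that left out 1 array, these are 2, 1, 1 and 2. The other such fits kept the lower direction, and over all 6 the means ran from -0.044 to 0.17, -0.090 to 0.14, -0.16 to 0.35 and -0.14 to 0.10. Fry tests a list against no change, not against other genes, so its other direction for the adherens junction (0.030), acinar transcription factor (0.020) and duct (-0.040) lists answers another question at unchanged means. The acute phase list was 0.063 with array weights. The cause was not tested, beyond fewer samples in fits without an array.

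The replicate numbers showed no pairing of the samples: same-numbered arrays had correlations of deviations of 0.041, 0.14 and -0.15. Arrays of unlike number ran from -0.18 to 0.15, and so few pairs cannot exclude a pairing. A replicate block gave 0 genes adjusted, 652 unadjusted (340 higher, 312 lower) and 18 lists. No signal over background or scan batch could be tested on these arrays.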

Other observations

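The list tests and the counts over other splits of the arrays were planned, while the tests of explanations for knockout array 1, Ctnnd1, the Xist and Y-linked transcripts and the genes near Ctnnd1 were chosen after the results were seen. By its mean, the PanIN and gastric-type mucosa list lay higher on every knockout array than on any wild-type array. PanINs are the duct-like precursor lesions of pancreatic cancer, and they express stomach-type genes. Its mean log2 level was 5.93 ± 0.016 on the knockout arrays and 5.74 ± 0.077 on the wild-type arrays (SD, n = 3), with 18 of 24 members higher. The exact permutation p was 0.1, the smallest that 3 arrays against 3 can give. Camera's adjusted p was 0.0874, and with an estimated correlation it was 0.731. The mean difference was 0.19, and 0.031 among genes above the median level (adjusted p = 0.7). It was 0.22 both above the 25th percentile of level (0.0274) and without wild-type array 2 (0.0309). Gkn3, a gastrokine of the stomach, differed by 2.03 (SE 0.64, adjusted p = 0.907), by 1.27 without knockout array 1 and by 1.11 with array weights, and Cldn18 by 0.62 (SE 0.15, adjusted p = 0.907). The separation of the list means rested on Gkn3, which was 7.76 on knockout array 1 and 3.58 to 4.86 on the wild-type arrays. Without Gkn3, the list mean of knockout array 1 would fall below that of wild-type array 2. By its mean, the acute phase and pancreatitis list was also higher on all 3 knockout arrays, at 7.12 ± 0.059 against 7.00 ± 0.069 (SD, n = 3, exact permutation p = 0.1). It was led by Reg3g at 0.86 and Fgb at 0.27, with a camera adjusted p of 0.318. Fgb was dim, with means of 3.90 in knockout and 3.63 in wild type, below the array medians over all rows (4.08 to 4.25). This separation rested on Reg3g: without it, the list mean of knockout array 2 would fall below that of wild-type array 2. The PanIN and acute phase lists were the 2 of 35 lists with complete separation, where chance gives 10% of lists. Both lists were fixed beforehand, but were picked out for description after their values were seen.

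Lists of signalling and metabolism gave no call in the fit as planned. Camera's adjusted p was 0.302 for ERK feedback genes (mean difference -0.02), 0.0587 for YAP and TEAD targets (-0.07), 0.829 for Wnt targets (mean -0.05, median 0.08) and 0.135 for laminins and integrins (-0.06). It was 0.78 for the sphingosine-1-phosphate pathway (0.017), 0.534 for p53 targets (8.2e-05, with camera lower), 0.0571 for glycolysis (-0.04), 0.775 for oxidative phosphorylation (0.06) and 0.78 for ribosomal proteins (0.07). Islet markers (-0.10, adjusted p = 0.0525), endothelial markers (0.08, 0.535), chemokines (-0.09, 0.169) and sex-linked genes (0.55, 0.318) were not called either. Of the 4 sex-linked genes measured, Xist was lower and 3 Y-linked genes were higher, with a median of 1.47. Because they go opposite ways with sex, their mean does not show that sex was balanced. With all 6 arrays some alternatives gave calls, all lower: glycolysis with the mean of rows (0.046), chemokines with array weights (0.00632), and islet markers (0.0364), YAP and TEAD targets (0.0271) and laminins and integrins (0.049) with a replicate block. Leaving out 1 array gave others. YAP and TEAD targets were lower without wild-type array 1 (-0.13, 0.00628) or 3 (-0.11, 0.0109), as were laminins and integrins (-0.14, 0.0124, and -0.11, 0.029), but without wild-type array 2 the means were 0.031 and 0.060. Without wild-type array 3, glycolysis (-0.05, 0.0495) and chemokines (-0.19, 0.0122) were lower and sex-linked genes higher (0.83, 0.0006). With all 6 arrays and an estimated correlation no list was called (smallest adjusted p = 0.731). MHC class II genes had -0.21 (0.0571), with H2-Ob at -0.64 (SE 0.50) and H2-Ab1 at -0.46 (SE 0.38). Their list mean was 9.62 on knockout array 1 against 8.35 and 8.44 on knockout arrays 2 and 3, and 9.05, 9.00 and 8.98 on the wild-type arrays. That list was called lower with the mean of rows (0.0436), the row of largest interquartile range (0.0468), ranks (0.0305), a replicate block (0.0271) and array weights (1.92e-06), and without knockout array 1 (-0.62, adjusted p = 2.75e-08). With an estimated correlation it was called neither with all 6 arrays (0.744) nor without knockout array 1 (0.253), and with the preset correlation it was not called after a further quantile normalization (0.224), with arrays shifted to 1 median (0.0977), among genes above the median level (0.232) or the 25th percentile (0.131), or over all rows (0.137). Without knockout array 2 its mean was 0.021.

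With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. For genes at an adjusted p under 0.05, all 10 splits gave at least the real count of 0, and the highest other split gave 1. For genes at an unadjusted p under 0.05, 4 splits gave at least as many as the real 708, and the highest other gave 4044. That split set knockout array 1 and wild-type arrays 1 and 3 against the rest, which points to a structure of the samples other than the labels. For lists, 8 splits gave at least the real 13, and the highest other gave 22.

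Knockout array 1 stood apart from knockout arrays 2 and 3. More leukocytes among its sorted cells is a candidate explanation: the smallest median gap of the 4 leukocyte lists was 0.690 log2 units in its favour. Cd74 was 11.70 against 10.62 and 10.46, and S100a8 8.98 against 6.99 and 6.82. On the wild-type arrays Cd74 was 11.23 to 11.29 and S100a8 7.77 to 8.56. The T and NK mean was 7.15 on knockout array 1 and 7.16, 6.75 and 7.22 on the wild-type arrays. These gaps do not tell more leukocytes on knockout array 1 from fewer on knockout arrays 2 and 3. Of the 74 leukocyte genes, 1 was also in another list and 57 lay above the median gene on knockout arrays 2 and 3, and a GFP gate would remove leukocytes without GFP. The endothelial and fibroblast lists were not raised with the leukocyte lists, and their higher median gap was -0.441. That goes against a smaller acinar share that raises all other cell types alike, but does not exclude it. Ribosomal protein (-0.376) and oxidative phosphorylation (-0.307) lists were also lower on knockout array 1. Its endothelial mean of 4.96 lay below its median gene (5.37), so a general shift of that array could hide a rise. An exchange of labels with a wild-type array of this series stays undecided. No wild-type array matched knockout arrays 2 and 3 better than its own group (largest excess in mean r -0.0086). That would count against an exchange only if r followed the labels. Knockout array 1 had a higher r with each wild-type array than with knockout arrays 2 and 3, so r cannot settle the question. A wrong label on knockout array 1 alone stays open too. Its r was 0.982, 0.973 and 0.980 with the wild-type arrays, and 0.958 and 0.95 with knockout arrays 2 and 3. Among the wild-type arrays r was higher, 0.984 to 0.986. The acinar transcription factor mean was 7.87 on knockout array 1 and 8.47 to 8.55 on the wild-type arrays, so array 1 also lay outside their range. No biological explanation was tested, because the pattern lies within 1 group.

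Ctnnd1 was not clearly lower on the arrays labelled knockout. Relative to 22 other adherens junction genes, the difference in Ctnnd1 between the groups was -0.210 (95% confidence interval -1.02 to 0.60, exact permutation p = 0.5, n = 3 per group). That interval holds both no change and a loss of 1 log2 unit. The direct interval from limma, -0.91 to 0.57, held no change but did not reach such a loss. A row that reads parts of the transcript outside the deletion stays open as an explanation, since only 1 row names Ctnnd1 alone and it cannot be set against another. Ctnnd1 RNA of other cells among the sorted ones and incomplete recombination, a biological possibility the design names through the genotype, were not tested.

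Knockout array 3 held both Xist and Y-linked transcripts. Xist was 9.97 there, 11.10 and 11.40 on wild-type arrays 1 and 2, and 3.56 to 3.98 on the other 3 arrays. The Y-linked genes Uty (1.71), Eif2s3y (1.93) and Kdm5d (1.32) lay above their means on wild-type arrays 1 and 2, by at least 1.32, and below their levels on the arrays with low Xist. RNA of male and female animals on 1 array is a candidate explanation. A raised background was ruled against: 2629 genes of like level had a median gap of 0.199, and 0.456% of them reached the smallest Y-linked gap. Xist was low and Uty high (8.15, 7.15 and 7.74) on knockout arrays 1 and 2 and wild-type array 3. By these transcripts the groups were not balanced for sex, so any difference between them can partly be one of sex.

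A hypothesis that genes near Ctnnd1 would hold more differences, as sequence linked to the floxed allele might give, was tested and stayed undecided. The 201 tested genes around Ctnnd1 held 9 at an unadjusted p under 0.05, more than 72.4% of 15777 such windows, and 8 of the 9 were olfactory receptors. Other splits of the arrays reached up to 98.6%.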
